A study of Rattus norvegicus with 3 samples.

How the data were processed

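Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on C6 cells, a rat glioma line, with an antibody against histone H3 trimethylated at lysine 4 (H3K4me3) and, separately, an antibody against acetylated histone H3 (H3ac). Sequencing was on an Illumina HiSeq instrument, per the labels' protocols. The series has 3 samples, which are 1 H3K4me3 library, 1 H3ac library and 1 library of input DNA that the labels assign to both. Only 2 files were analysed, the peak list of each antibody. The input was not analysed here as a file of its own.

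Reads were mapped to the rat genome build rn4, per the submitters' processing notes. Those notes name BWA for the H3K4me3 and input libraries and Bowtie for the H3ac library, so the aligner differed between the marks. Peaks were called with MACS, per the file headers, and the version is not given in the sources used here. The header of the H3K4me3 list carries the run name H3K4me3_inp, read here as a call against the input, and an mfold of 16. The header of the H3ac list names its run C6K9ac2 and no control. K9ac is a usual short form for acetylated lysine 9, whereas the label gives a general acetyl-H3 antibody. The mark is called H3ac here, as the label gives it, and which of them the library holds was not settled. Each list has 5 columns, and its only measurement is a score per peak, as deposited, which was read from its lowest values, 50.03 for H3K4me3 and 50.05 for H3ac, as being on the scale of 10 times the negative log10 of p. The score is the authors' own. Within its list it was used to rank, bin and filter peaks and to give medians, and between the lists only the ranks of paired peaks were correlated. Score values were not compared between the lists. It depends on the depth of the library, which is unknown, as the lists give no read counts. In the H3K4me3 list 3217 peaks had a score of exactly 3100 and 272 had a higher one, up to 3233.06. Those at exactly 3100 had a median width of 4139 bp, against 3266 bp for those above it, so the order of scores at the top of the scale was not used to say which peak is strongest.

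Peak positions are given in rn4 coordinates, counted from 1. No gene annotation of rn4 was used here, and coordinates were not converted between builds. The planned analyses of gene starts and of gene lists were therefore not run, and no peak is assigned to a gene, exon or promoter.

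From the lists the number, width and covered length of peaks were computed, with the share of peaks of each mark that had at least 1 bp in common with a peak of the other. Such peaks are called shared and the rest unshared. The chance level came from 1000 circular shifts of the H3ac list, with an independent offset for each chromosome, and chromosome lengths were taken as the end of the last peak of either list. Peaks with exactly 1 partner, whose partner also had exactly 1, were treated as pairs. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only and treat peaks as independent. With 1 library per antibody there was no replicate error, and no test was made between libraries. Correlations of scores and widths are Spearman coefficients across peaks, which are not independent replicates.

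The 5 highest scoring and the 5 widest peaks of each list, the 5 widest H3K4me3 peaks without H3ac and the 5 highest scoring H3ac peaks without H3K4me3 were chosen for naming by a rule. The rule, the main comparisons and the alternatives were fixed before the data were examined. Some descriptions were not named in that plan. Among them are the shares by score, the distances to the nearest peak of the other mark and the nesting of pairs. The widths of pairs by score, the counts of several partners and the window on chromosome 17 were not named either. The alternatives were a stricter threshold (the top 50% of each list by score), merging of peaks less than 500 bp or less than 2 kb apart, coverage of at least 50% of the peak, a neighbour within 1 kb, lists of equal length, windows of 1 kb around peak centres and omission of chromosome X. No peaks on unplaced sequences or the mitochondrion were listed.

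The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Overlap counts equalled those of bedtools 2.31.1. The overlap functions were tested on simulated data in which 8000 peaks were placed on H3K4me3 peaks and 2000 in gaps, and exactly 8000 were recovered. The permutation of runs of unshared H3ac peaks was tested on 20 simulated lists. The count exceeded every permutation in 0 of the 20 lists without planted runs and in 20 of the 20 with them.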

Results

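H3K4me3, a modification known to mark active gene starts, and H3ac, a modification of open and transcribed chromatin, were mapped across the genome of C6 rat glioma cells. The comparison addressed where both modifications lay in the same cells and how far their maps coincided. Each mark was represented by 1 library and 1 peak list, so no value below has a replicate error, and the intervals given cover counting error only. The read depth behind the lists is unknown. The H3ac list carries a run name with K9ac, so the acetylated residues it stands for are open.

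The H3K4me3 map was made of more and narrower regions than the H3ac map. It held 17748 peaks on 21 chromosomes, with a median width of 2090 bp and quartiles of 1196 and 3169 bp. The H3ac map held 12357 peaks on the same number of chromosomes, with a median width of 2843 bp and quartiles of 2106 and 3911 bp. H3K4me3 peaks were 1.44 times as numerous, whereas the H3ac peaks were 1.36 times as wide at the median. The covered lengths were close, at 43.1 Mb for H3K4me3 and 40.9 Mb for H3ac. Very wide regions were more numerous in the H3ac map, which had 169 peaks over 10 kb, against 42 in the H3K4me3 map. The closest neighbours also differed, since 1048 H3K4me3 peaks but 304 H3ac peaks followed the preceding peak by less than 500 bp. The narrowest peak had 272 bp in the H3K4me3 map and 694 bp in the H3ac map. Among peaks paired one to one the median widths were closer, at 2727 bp for H3K4me3 and 2917 bp for H3ac. The libraries were processed with different aligners and called separately, and only the H3K4me3 header points to a call against the input. Whether any of this changed number or width was not tested.

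Most H3ac regions lay on H3K4me3. Of the H3ac peaks, 10535 overlapped an H3K4me3 peak, which was 85.3% (95% interval 84.6 to 85.9). Of the H3K4me3 peaks, 11191 overlapped an H3ac peak, which was 63.1% (62.3 to 63.8). In lists shifted along the chromosomes the mean was 485 H3ac peaks, with a highest value of 587, and 505 H3K4me3 peaks, with a highest value of 627. The observed overlaps were therefore 21.7 and 22.1 times the shifted means. Shifts of only 20 to 200 kb, added after the data were seen and keeping the regional density of peaks, left 9.40-fold and 9.53-fold. Together both maps covered 53.3 Mb, of which 30.7 Mb carried both marks, a Jaccard index of 0.57. The order of the shares turned when the H3K4me3 list was shortened to its 12357 highest scoring peaks, which changes its length and removes its weakest peaks at once. Then 80.0% of H3K4me3 peaks and 77.7% of H3ac peaks were shared. In the full lists, too, the number of shared peaks was higher for H3K4me3 (11191 against 10535). With lists of equal length the shares follow the numbers of shared peaks, so the turn by itself does not rank the marks.

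The share of overlapped peaks rose with the score in both maps. Among H3K4me3 peaks with a score of 50 to 100, 21.0% (19.6 to 22.6) overlapped H3ac. The share was 43.9% (41.7 to 46.1) at scores of 200 to 500 and 95.7% (95.2 to 96.2) at 2000 or more. Among H3ac peaks, 60.4% (58.6 to 62.1) lay on H3K4me3 at scores of 50 to 100 and 99.0% (98.5 to 99.4) at 500 to 1000. Scores are not on a common scale between the lists, so the curves can be read only along each list. At scores of 500 to 1000, 631 of 1521 H3K4me3 peaks had no H3ac peak, and at 1000 to 2000 it was 683 of 2921. Such peaks were few only at the top of the scale, at 266 of 6252 with a score of 2000 or more. Of 3489 H3K4me3 peaks with a score of 3100 or more, 59 had no H3ac peak. The H3ac map had 89 peaks in that range, and every one of them overlapped H3K4me3, with a lower 95% limit of 95.9%.

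**Figure D1:**
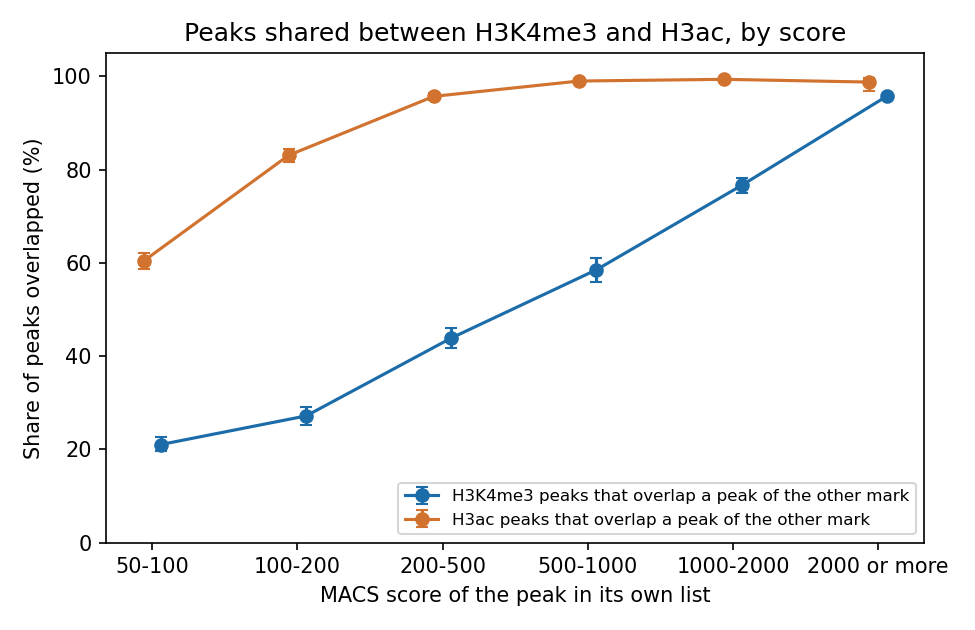
Share of peaks that overlapped a peak of the other mark (vertical axis, percent) by the MACS score of the peak in its own list (horizontal axis, no unit), for H3K4me3 in blue and H3ac in orange, with exact binomial 95% intervals as bars. The H3K4me3 share rises from 21.0% to 95.7%, and the H3ac share rises from 60.4% to 99.0% by scores of 500 to 1000.

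Regions with both marks were wider than regions with one. Shared H3K4me3 peaks had a median width of 2672 bp (quartiles 1863 and 3727) and unshared ones 1188 bp (879 and 1775), a ratio of 2.25. Shared H3ac peaks had a median width of 2990 bp (2269 and 4047) and unshared ones 1917 bp (1542 and 2740), a ratio of 1.56. The median scores went the same way, at 2153 for shared and 148 for unshared H3K4me3 peaks, and at 291 and 78.4 for H3ac peaks. Within the top 50% of each list by score, with overlap counted between the shortened lists, the width ratios were 1.24 for H3K4me3 and 1.08 for H3ac. Unshared peaks of that setting include peaks whose partner fell in the lower 50% of the other list. These ratios therefore do not show how far the contrast holds among high scoring peaks. Most unshared regions had no peak of the other mark within 2 kb. The nearest H3ac peak was at a median of 37.3 kb from an unshared H3K4me3 peak, and 750 of the 6557 (11.4%) had one within 2 kb. The nearest H3K4me3 peak was at a median of 21.4 kb from an unshared H3ac peak, and 140 of the 1822 (7.68%) had one within 2 kb.

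**Figure D2:**
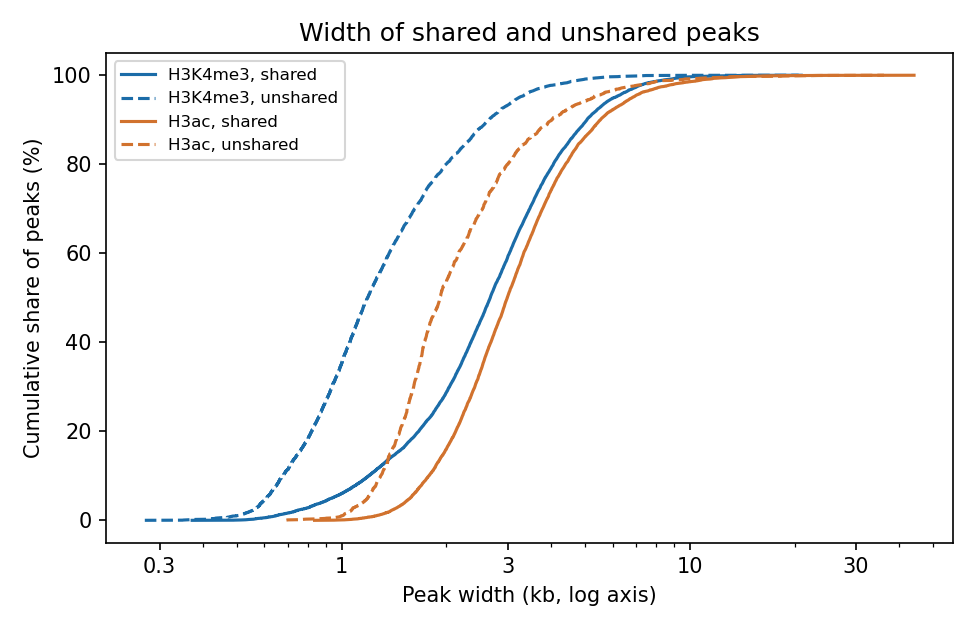
Cumulative share of peaks (vertical axis, percent) by peak width (horizontal axis, kb, log axis) for H3K4me3 in blue and H3ac in orange, with solid lines for shared and dashed lines for unshared peaks. The unshared H3K4me3 peaks lie farthest to the left, with a median of 1188 bp, and the shared H3ac peaks farthest to the right, with a median of 2990 bp.

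Where the maps met, the centres of the peaks lay closer than those of peaks that overlap by chance. There were 9764 pairs of 1 H3K4me3 and 1 H3ac peak. Their centres were 157 bp apart at the median (quartiles 68 and 319), and 87.0% lay within 500 bp. For pairs that overlapped after 100 circular shifts, a comparison added after the data were seen, the median offset was 1234 to 1608 bp per shift and 17.9% lay within 500 bp. The H3ac peak was the wider in 65.5% of pairs, with a median difference of 208 bp and quartiles of -159 and 574 bp. The H3K4me3 peak lay wholly inside its H3ac partner in 4543 pairs, the reverse held in 1200, and 4021 pairs overlapped in part. Across pairs the widths had a Spearman coefficient of 0.82 and the scores one of 0.67. The correlation of scores fell to 0.43 in the top 50% of each list. That filter narrows the range of scores and keeps all 3217 H3K4me3 peaks tied at 3100. The fall by itself therefore does not show a weaker relation at high scores. Pairs whose H3K4me3 score was 200 to 500 had a median H3ac width of 1882 bp and H3K4me3 width of 1469 bp, whereas at 2000 or more these were 3514 and 3480 bp.

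Some H3ac peaks overlapped several H3K4me3 peaks. An H3ac peak overlapped at least 2 H3K4me3 peaks in 654 cases and as many as 7, while the reverse was seen for 70 H3K4me3 peaks and never with more than 2. More H3K4me3 than H3ac peaks followed the preceding peak by less than 500 bp (1048 against 304). No such count is given for merged peaks, so separate H3K4me3 regions were not told apart from 1 region split by the calling. The widest H3ac peak, 44.1 kb on chromosome 7 from 123646373 to 123690455, overlapped 7 H3K4me3 peaks. Another, 35.5 kb on chromosome 7 from 11042484 to 11077941, overlapped 5. On chromosome 19, an H3ac peak of 43.0 kb from 14752548 to 14795579 overlapped 1 H3K4me3 peak and had a score of 247, near the median of its list (230.3). The fifth by width, 24.7 kb on chromosome 3 from 25640500 to 25665243, overlapped 2 H3K4me3 peaks. That region of chromosome 3 also held the widest H3K4me3 peak, 20.9 kb from 25644174 to 25665082. Other wide H3K4me3 peaks with H3ac were 18.4 kb on chromosome 2 from 120966629 to 120985027, 17.4 kb on chromosome 3 from 135831689 to 135849080, and 14.8 kb on chromosome 2 from 180603229 to 180618012.

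Wide regions with 1 mark alone were few. Among unshared peaks, 1 H3K4me3 and 15 H3ac peaks were over 10 kb. The H3K4me3 peak was 20.6 kb on chromosome 1 from 215571859 to 215592412, with a score of 1184. The next widest H3K4me3 peaks without H3ac were 9.94 kb on chromosome 11 from 25435291 to 25445233, 9.67 kb on chromosome 4 from 136246818 to 136256491, 8.67 kb on chromosome 4 from 62916248 to 62924915, and 7.48 kb on chromosome 10 from 106952479 to 106959961. The H3ac peak with the highest score and no H3K4me3 was also the third widest of its list, 36.1 kb on chromosome 17 from 49622395 to 49658525, with a score of 2828. It was followed by 7.29 kb on chromosome 3 from 156709 to 164001, 11.7 kb on chromosome 3 from 9481529 to 9493210, 12.2 kb on chromosome 14 from 48747749 to 48759918, and 3.20 kb on chromosome 12 from 12281109 to 12284310.

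The 5 peaks listed with the highest scores in each map all carried both marks. For H3K4me3 these lay on chromosome 8 from 4845402 to 4850315 and from 61003388 to 61007502, on chromosome 4 from 174862277 to 174866329, on chromosome 19 from 53436448 to 53440362, and on chromosome 3 from 158766563 to 158769846. All of them had a score of 3233.06. For H3ac they lay on chromosome 5 from 135266946 to 135273962, chromosome 14 from 101625689 to 101629810, chromosome 7 from 120205580 to 120211677, chromosome 12 from 23227032 to 23230880, and chromosome 20 from 43076917 to 43083790, with scores of 3185 to 3230.05. The 3217 H3K4me3 and 81 H3ac peaks at exactly 3100 were wider at the median than those above it (4139 against 3266 bp and 9008 against 5905 bp), so these 5 are not shown to be the strongest.

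The stretch of chromosome 17 around the 36.1 kb H3ac peak held many H3K4me3 peaks without H3ac. Between 48.1 and 51.1 Mb there were 59 H3K4me3 peaks, of which 40 (67.8%) had no H3ac peak, against 36.9% in the whole map. The 40 had a median score of 721 and a median width of 1670 bp, against 148 and 1188 bp for all unshared H3K4me3 peaks. The same stretch held 24 H3ac peaks, of which 5 (20.8%, against 14.7% in the whole map) had no H3K4me3, among them a second wide one of 23.3 kb. The window was drawn around a peak that the naming rule gave. That peak is among the 5 without H3K4me3, so the choice of the window raised the 20.8%. The H3K4me3 peaks of the window were noticed only in the map.

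**Figure D3:**
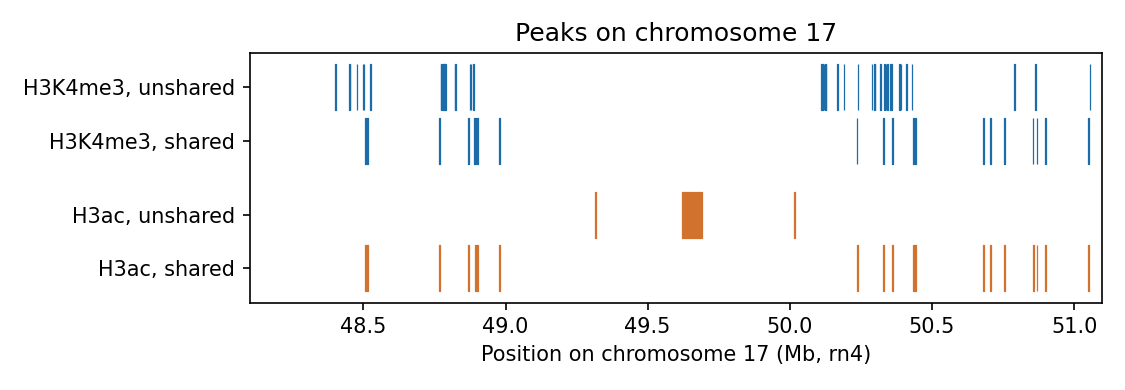
Peaks of H3K4me3 (blue) and H3ac (orange) between 48.1 and 51.1 Mb of chromosome 17, build rn4 (horizontal axis, Mb), in separate rows for shared and unshared peaks, each bar spanning a peak at scale except that the narrowest are drawn at the width of a line. The 40 unshared H3K4me3 peaks lie in groups on both sides of the wide unshared H3ac peaks near 49.6 Mb.

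Both marks were unevenly spread over the chromosomes and in a similar order. Chromosome 12 carried 12.2 H3K4me3 and 9.25 H3ac peaks per Mb, and chromosome 10 carried 12.1 and 9.45. Chromosome X had the lowest density of both, with 3.03 H3K4me3 and 1.86 H3ac peaks per Mb. Over all chromosomes there were 0.70 H3ac peaks per H3K4me3 peak. The ratio was highest on chromosome 10, at 0.78 (95% interval 0.72 to 0.85), and lowest on chromosome X, at 0.62 (0.53 to 0.71). The interval excluded the overall ratio on 3 chromosomes, which were 10, above it, and 2 and 4, below it, at 0.63 each. In the top 50% of each list the ratio of chromosome 10 was 0.70, equal to that of all chromosomes, and that of X was 0.53. Neighbouring peaks are not independent, so the intervals are narrower than the true uncertainty.

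**Figure D4:**
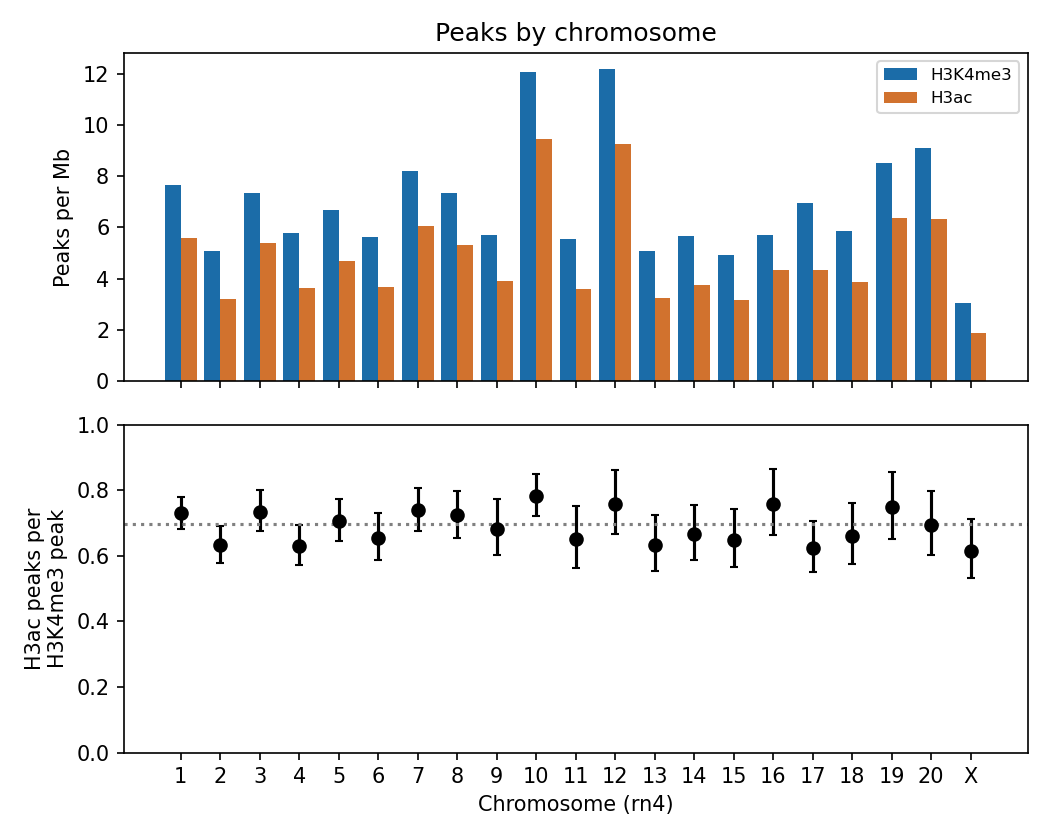
Peaks per Mb of H3K4me3 (blue bars) and H3ac (orange bars) on each chromosome, and below it the number of H3ac peaks per H3K4me3 peak (no unit) with exact binomial 95% intervals as bars and the value of all chromosomes, 0.70, as a dotted line. Chromosomes 10 and 12 have the highest densities and chromosome X the lowest.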

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

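Of 55 alternative values, 18 stayed within the interval of the reported value, or within 1.5 times it for counts and densities, and 37 moved. The interval was the exact binomial one only for shares and chromosome ratios. Widths, lengths, scores, offsets, coefficients and fold values had intervals of another kind, which are not given here. A change of sign was possible only for the correlation coefficients and the score differences, and none of them changed sign. Each alternative is the reported value recomputed with 1 choice changed. The cause of a shift was not tested, except that the stricter threshold and merging hold fewer peaks by construction. With the top 50% of each list by score there were 8874 H3K4me3 and 6178 H3ac peaks, median widths of 3117 and 3542 bp, covered lengths of 31.2 and 25.5 Mb, 90.2% of H3ac peaks shared, width ratios of shared to unshared peaks of 1.24 for H3K4me3 and 1.08 for H3ac, and median score differences of 1199 and 252. Overlap in this setting was counted between the shortened lists, so a peak whose partner fell in the lower 50% of the other list counts as unshared. For pairs, this setting gave coefficients of 0.43 for scores and 0.79 for widths and a median offset of 192 bp. It gave 0.70 H3ac peaks per H3K4me3 peak on chromosome 10 and 1.30 H3K4me3 peaks per Mb on X. Merging of peaks less than 500 bp apart gave median widths of 2225 bp for H3K4me3 and 2891 bp for H3ac, and merging under 2 kb gave 2359 and 2945 bp, with covered lengths of 44.4 and 41.6 Mb and 64.6% and 86.5% of peaks shared. A coverage of at least 50% gave 62.3% and 80.9% shared, an H3ac width ratio of 1.44, a coefficient of widths of 0.88 and an offset of 150 bp. The shared part was 65.7% of H3K4me3 peaks with the other mark within 1 kb, and 56.4% and 80.4% (H3ac) for 1 kb around the centres. For lists of equal length it was 80.0% and 77.7% (H3ac), where the order of the shares turned. After the data were seen, shifts of 20 to 200 kb were added, which gave 9.53-fold for H3K4me3 and 9.40-fold for H3ac, as was a ranking of scores of exactly 3100 as highest, which gave a coefficient of 0.69. The alternatives at gene starts were not run, as no rn4 annotation was used. No paired analysis was possible because each group has 1 sample. The lists give no read counts, so whether a region without a call lacks the mark or falls below the depth of its library cannot be decided.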

Other observations

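All tests in this part were chosen after the result was seen.

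Counting the peaks of both marks together, the windows of 1 Mb with the most peaks were 10 to 11 Mb on chromosome 7, with 55 H3K4me3 and 43 H3ac peaks, 3 to 4 Mb on chromosome 20, with 48 and 37, 208 to 209 Mb on chromosome 1, with 47 and 35, 19 to 20 Mb on chromosome 16, with 47 and 30, and 56 to 57 Mb on chromosome 10, with 44 and 29. At the other end, 9 stretches over 5 Mb between peaks had no peak of either mark. The longest were 10.7 Mb on chromosome X from 105730846 to 116429767 and 8.93 Mb on chromosome 19 from 668959 to 9597927. On chromosome 2, stretches of 6.77 and 6.43 Mb were parted by peaks within less than 1 kb.

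H3ac peaks without H3K4me3 followed each other in long runs. In the order of the H3ac list, 192 of the 1822 unshared peaks lay in runs of at least 5. When the unshared label was permuted 1000 times among peaks of like score, the mean was 4.86 and the highest count 31, and 26 when width was matched too (permutation p = 0.001, the smallest that 1000 draws can give, one-sided, across peaks of 1 library). Score and width of the single peak therefore do not account for the runs. Counting only runs with no H3K4me3 peak in between, the longest were 20 peaks on chromosome 1 from 49955230 to 52465479, 17 on chromosome X from 128856935 to 130541173, and 11 on chromosome 1 from 31281606 to 33784508, with median scores of 65.6, 85.0 and 69.1. In the order of the H3ac list, 140 peaks in runs remained without these 3 blocks. Extra copies of these segments in C6 cells, the different aligners and a regional gain of H3ac alone all remain open. So does a difference in control, since the header of the H3ac list names none, although the labels assign the input to both libraries. None of them was tested, since these blocks hold no H3K4me3 peak by definition and the lists give no read coverage.

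H3K4me3 peaks without H3ac also followed each other in runs. In the order of the H3K4me3 list, 824 of the 6557 lay in runs of at least 5, against a mean of 478 and a highest count of 621 in 1000 permutations within score strata, and 615 with width matched too (permutation p = 0.001, one-sided, the smallest possible). A single threshold on peaks of like score and width therefore does not account for all of it. The longest run with no H3ac peak in between had 16 peaks on chromosome 1 from 111590415 to 113957542, with a median score of 94.7. Median scores of such runs ranged from 58.9, on chromosome 16, to 1813, on chromosome 20. The stretch of chromosome 17 described above held a run of 7 peaks from 48771272 to 48823966 and a run of 6 from 48400982 to 48502685. The median scores of these runs were 1123 and 882. It also held a run of 6 peaks from 50110443 to 50192144, with a median score of 569. Runs of 5 lay there from 50238591 to 50320439 and from 50331733 to 50358676, with median scores of 319 and 718. Regional differences in H3ac, in mappability or in copy number remain open and were not tested.

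Chromosomes with more H3K4me3 peaks per Mb had more H3ac peaks per H3K4me3 peak. Over 21 chromosomes Pearson's r was 0.77 (permutation p = 2e-05, 8e-05 adjusted over the 4 settings tried) and Spearman's rho 0.76 (permutation p = 0.0002, adjusted 0.0008). Without chromosomes 10 and 12, the farthest from the median density, r was 0.68 (permutation p = 0.001, adjusted 0.0013). Without X it was 0.74. In the top 50% of each list rho was 0.34 (permutation p = 0.1) and r 0.32 (p = 0.2, permutation). Peaks in the lower 50% may therefore carry much of the relation, and 21 chromosomes do not decide it. This filter cannot single out peaks near the calling threshold. It cuts at the median scores, 1111 for H3K4me3 and 230 for H3ac, against lowest scores near 50, and it leaves fewer peaks per chromosome.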
